A study of Homo sapiens with 6 samples.

How the data were processed

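Total RNA of T24 cells was sequenced after 24 h with si-NC or si-KNSTRN, which had been added once the cells had attached for 24 h, per the labels' protocols. The labels name a SMARTER mRNA library kit. Groups and replicate numbers were taken from the sample titles, with 3 libraries per group, which the series' design text calls biological replicates. The siRNA sequences, the strand setting, the treatment of reads with several alignments and the annotation release are not given in the sources used here.

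The values are the authors' deposited read counts per gene, whole numbers with no normalization, 1 column per library. Per the submitters' processing notes, FastQC 0.11.5, fastp 0.20.0, HISAT2 2.0.1 and featureCounts (no version) were used with the build GRCh38; the notes give no order or settings. The table lists 20442 genes by symbol, and 3984 of them had no read in any library. Totals ran from 16386799 to 20596074 reads per library, a floor of 0.146 to 0.183 CPM for 3 reads, which covers counting error only because the reads carry no molecular identifiers in the sources used here. Replicate pairs were compared by chi-square per degree of freedom, which ran from 2.21 to 10.6, so that no pair agreed within sampling noise and none was merged.

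From these counts, edgeR 4.0.16 in R 4.3.3 was run with its low-count filter (filterByExpr, minimum count 10), which left 12650 genes, TMM scaling and the two-sided quasi-likelihood test of si-KNSTRN against si-NC without further terms. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 5.47%. Levels are TMM-scaled CPM as mean ± SD over 3 libraries, and log2 fold changes come from edgeR with their standard errors. Without strand information, reads of overlapping genes cannot be told apart: 23 of the 157 named genes overlap another tested gene, among them DEPP1 (RASSF4), FAS (ACTA2), SLC5A3 (MRPS6), TYMS (ENOSF1), IL24 (FCMR) and LOX (SRFBP1).

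The 36 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 genes tested were compared with all other genes by camera in limma 3.58.1 on voom values, with the preset correlation of 0.01, two-sided and adjusted over 32 lists. The named genes were KNSTRN, the 12 largest rises and 12 largest falls with an average log2 CPM of at least 2 and separated groups, the 4 members of each list with the smallest p, and 11 genes of autophagy, lysosome, stress and spindle named in advance. Gene coordinates came from the RefSeq table of GRCh38. Transcript sequences came from GENCODE release 29, in which 19203 of the 20442 symbols were found, with 1 transcript per gene. A gene was treated as having a near-identical copy if at least 90% of its 50-base windows occurred in another gene. Named genes that share a smaller but large part of their windows (CTSD, ATP6V0C and HSPA1B) are pointed out in the text.

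The motif search was added after the fold changes had been seen. For 12022 tested genes with a 3' UTR of at least 50 bases (95.0%), the log2 fold change, limited to 2 in either direction, was regressed on the presence of each of 15611 words of 7 bases found in at least 100 genes, beside 3' UTR length and GC content, transcript length and GC content and expression. The regression and the summaries were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The test and the list test were tested on simulated data first. In counts simulated for si-KNSTRN against si-NC from the real means and library sizes (12584 genes tested), edgeR recovered 62% of 50 genes changed 1.25-fold, 90% of 50 changed 1.5-fold, 92% of 50 changed 2-fold and 100% of 50 changed 4-fold, with 16 false calls among 12450 unchanged genes. In 20 simulated lists of 30 genes, the single list shifted by 1.25-fold was called and no other. Genes were drawn independently there, so false calls through correlation between genes were not tested. All genes outside the shifted list were simulated without change, unlike in the real data. The power of the list test against a background of changed genes was therefore not tested. In the motif regression on 12022 genes, a word planted with a coefficient of -0.2 ranked 1 of 15611 and was recovered at -0.179.

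Alternatives were DESeq2-type (median-of-ratios) factors, library size alone and upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of CPM of at least 1 in 3 libraries, the replicate number as a block, each library left out in turn, stricter thresholds, and for the lists fry and an estimated correlation. Counts without genes that hold TGAGTA in the 3' UTR and without genes with a near-identical copy were added after the data had been seen.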

Results

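RNA sequencing was used to compare T24 cells, an established line of human bladder cancer epithelium, that had been treated for 24 h with a small interfering RNA against KNSTRN (si-KNSTRN) or with a control siRNA (si-NC). Each group held 3 libraries, described by the submitters as biological replicates. The deposited table gave raw read counts for 20442 genes. The si-NC libraries 1 to 3 held 20596074, 16386799 and 18305894 counted reads, and the si-KNSTRN libraries 1 to 3 held 19717513, 17870543 and 18133055. A total of 3 reads, the most that a count of 0 allows, corresponded to 0.146 to 0.183 CPM (read counts scaled to library size) across libraries, for counting error alone. The first principal component held 78.7% of the variance and separated the groups, with si-NC libraries between -30.5 and -30.1 and si-KNSTRN libraries between 25.4 and 36.1.

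The comparison asked how loss of KNSTRN, which encodes the mitotic spindle and kinetochore protein kinastrin, changed the transcriptome of these cells, with autophagy, lysosomes and reactive oxygen species named as the study's subjects. KNSTRN (chromosome 15, 40382721 to 40394288, GRCh38) had 777, 663 and 762 reads in si-NC libraries 1 to 3 and 269, 245 and 226 reads in si-KNSTRN libraries 1 to 3. Its level fell from 40.5 ± 1.92 CPM to 13.1 ± 0.821 CPM (SD, n = 3 each), a log2 fold change of -1.62 (SE 0.07, adjusted p = 1.7e-11 by edgeR). Inflammatory cytokine genes (29 of 34 tested), immediate early genes (22 of 29) and cytosolic heat shock genes (18 of 19) rose in si-KNSTRN cells. Genes of glycolysis and the hypoxia response (31 of 38), cytosolic ribosomal protein genes (51 of 74) and genes of G2/M and mitosis (44 of 75) fell. These groups were called by camera, a test against all other genes, but not with an estimated correlation between genes (adjusted p from 0.23 to 0.50). That setting also has fewer degrees of freedom. Genes of autophagy receptors, lysosomal hydrolases and lysosomal membrane proteins changed in both directions, as did the genes tested as a whole. None of these 3 lists was called by camera (adjusted p = 0.14, 0.78 and 0.78). Core autophagy genes (22 of 49 higher, 11 lower) were not called either (camera adjusted p = 0.10). V-ATPase subunit genes (14 of 21 higher, 2 lower) and ferroptosis and iron genes (17 of 28 higher, 6 lower) were called higher by camera (adjusted p = 0.0071 each). With an estimated correlation, camera gave these 2 lists an adjusted p of 0.27 each.

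Of 12650 genes tested by edgeR's quasi-likelihood test, 3946 were higher and 3959 lower in si-KNSTRN cells at an adjusted p under 0.05. The median absolute log2 fold change of these genes was 0.42, and 384 of the higher and 430 of the lower genes differed by at least 2-fold.

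**Figure D1:**
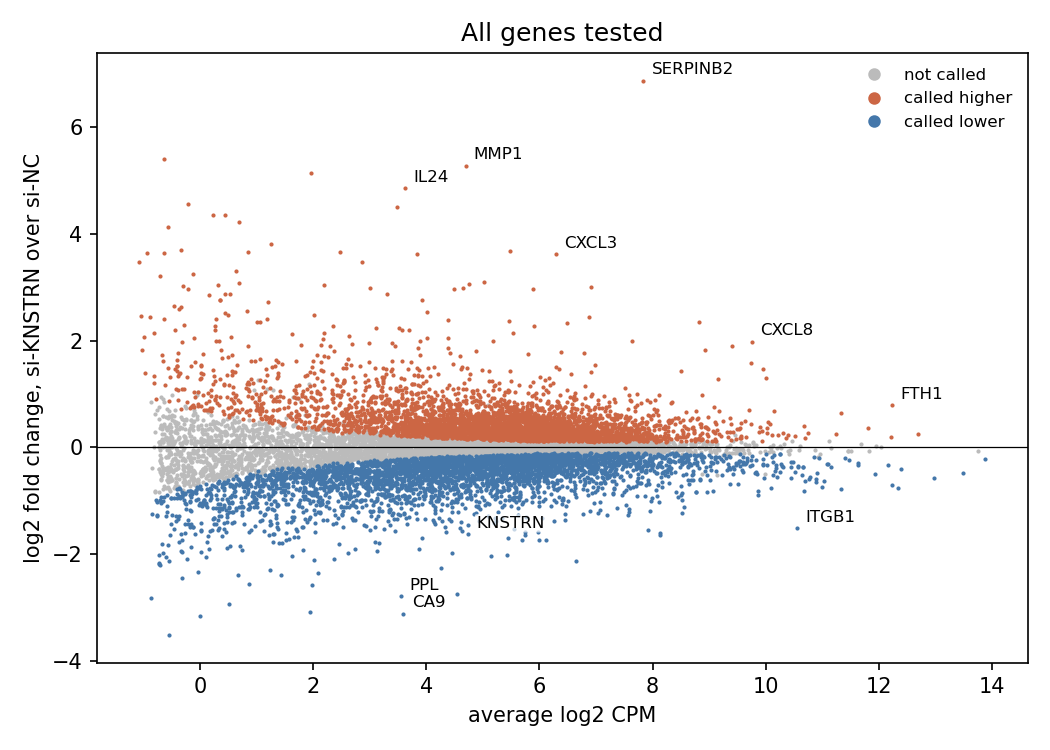
Log2 fold change of si-KNSTRN over si-NC against average log2 CPM for the 12650 genes tested, each point a gene. Orange points mark the 3946 genes called higher, blue points the 3959 called lower and grey points those not called. SERPINB2 stands highest at 6.86 and CA9 is the named gene farthest below 0 at -3.11.

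The largest rise among named genes was that of SERPINB2 (chromosome 18, 63887705 to 63903888, GRCh38), which encodes plasminogen activator inhibitor type 2. It went from 3.85 ± 0.348 to 451 ± 49.7 CPM (SD, n = 3), a log2 fold change of 6.86 (SE 0.10, adjusted p = 1.3e-17). MMP1, an interstitial collagenase gene (chromosome 11, 102789919 to 102798160), rose from 1.29 ± 0.364 to 49.9 ± 5.18 CPM, and the cytokine gene IL24 from 0.799 ± 0.275 to 23.4 ± 5.30 CPM. Log2 fold changes of 3.62 for the chemokine gene CXCL3, 3.62 for the stress cytokine gene GDF15, 3.10 for the prostaglandin synthase gene PTGS2 and 3.06 for the thrombomodulin gene THBD followed. ESM1, the anti-apoptotic gene BCL2A1 and the activin antagonist gene FST rose by log2 fold changes of 3.00, 2.98 and 2.97. XAGE1B (log2 fold change 4.51, SE 0.59) and RGPD5 (3.04, SE 0.63) also passed the rule for naming, but both share their sequence with near-identical copies, and their values are uncertain. XAGE1B had 398, 672 and 114 reads in si-KNSTRN libraries 1 to 3, and RGPD5 had 65, 58 and 319.

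The largest fall among named genes was that of CA9, a carbonic anhydrase gene induced by hypoxia (chromosome 9, 35673928 to 35681159, GRCh38), from 21.7 ± 2.06 to 2.50 ± 0.815 CPM (SD, n = 3; log2 fold change -3.11, SE 0.15, adjusted p = 5.7e-11). PPL, which encodes the cornified envelope protein periplakin, fell by 2.79, PPFIA4 by 2.75, the potassium channel subunit gene KCNS1 by 2.35 and the myo-inositol transporter gene SLC5A3 by 2.27 on the log2 scale. LOC124901807, PRRT2 and ARL6IP6 had log2 fold changes of -2.11, -2.08 and -2.04. The glycolytic gene ALDOC (-2.01), NUDT18 (-1.99) and DEPP1 (-1.97) were also among the 12 largest falls. The 3' untranslated region (UTR) of NUDT18 holds the sequence CTGAGTAA, those of ARL6IP6 and DEPP1 hold its first 7 bases and that of ALDOC holds TGAGTA, a motif met more often among genes called lower. Of the 3761 searched genes called lower, 34.1% held TGAGTA in the 3' UTR, against 18.8% of the 3783 called higher and 26.2% of the 4478 not called. Of 364 genes with CTGAGTAA, 174 were called lower and 72 higher, and of 8851 genes without TGAGTA, 2477 and 3070. There were 1032 genes with CTGAGTA but not the 8 bases (420 lower and 214 higher), 686 with TGAGTAA but not CTGAGTA (306 and 130) and 1089 with TGAGTA alone (384 and 297). Named genes that rose held TGAGTA too, among them ESM1, HERPUD1 and HSPH1 with TGAGTAA and DUSP1, FKBP4, OSTM1, TBX2 and RGPD5 with TGAGTA alone. The site is not marked at every gene in the passages below. Among named falls there, SPC24, DDX58, VLDLR, ERO1A, RRAGC, TJP1 and H2AC11 hold CTGAGTA, and SCD holds CTGAGTAA. SCARB2 and CENPU hold TGAGTAA, and TMEM106B, IFIT2 and LAMP2 hold TGAGTA alone.

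**Figure D2:**
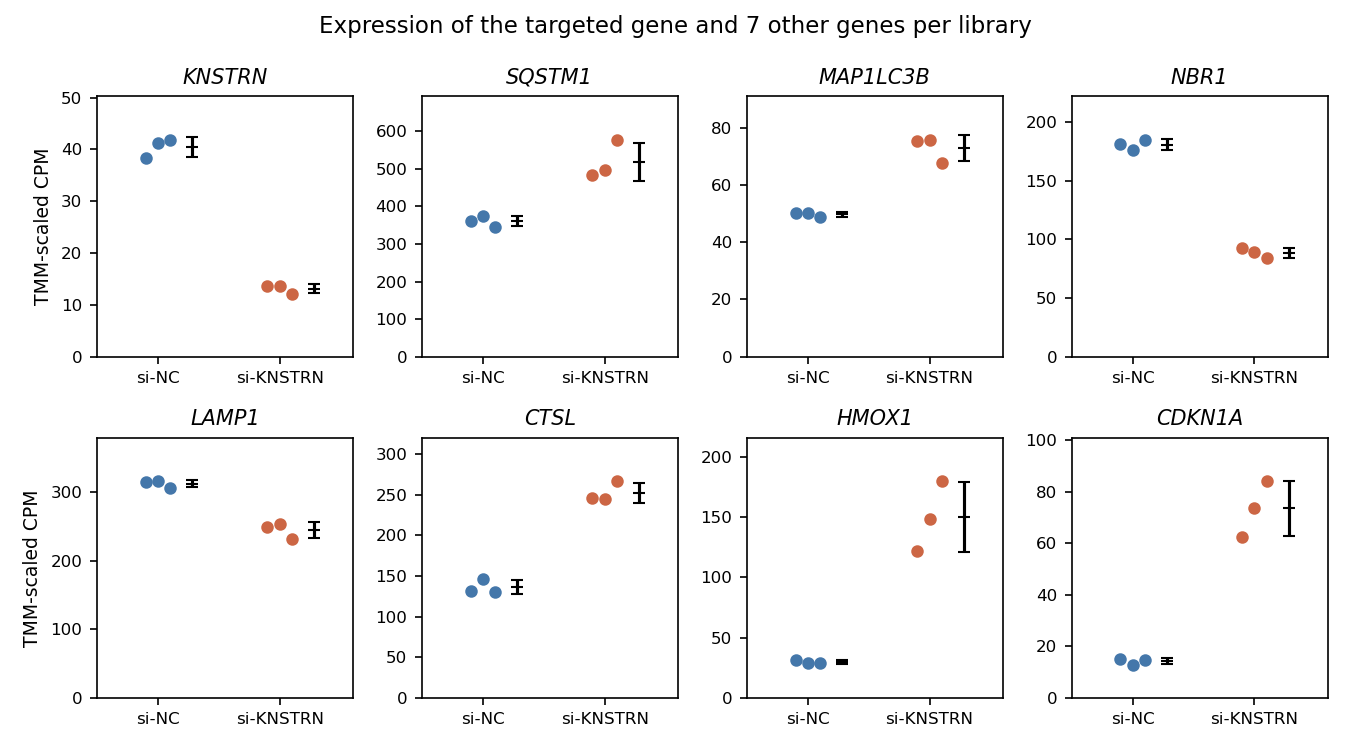
TMM-scaled CPM of KNSTRN and of 7 other genes in each library, on axes that start at 0. Coloured points are the 3 libraries of a group, and the black mark beside them is the mean with its SD. KNSTRN lies between 12.2 and 13.6 CPM in the si-KNSTRN libraries and between 38.3 and 41.8 CPM in the si-NC libraries, and SQSTM1 lies between 483 and 577 CPM against 346 to 374 CPM.

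Gene lists fixed before the data were examined were tested as groups with camera, at a preset correlation of 0.01 between genes. Of 32 lists with at least 5 genes tested, 7 were called higher and 4 lower. None of the 11 calls held when the correlation was estimated from the residuals in camera, where 5 lists had an unadjusted p under 0.05, and that adjusted p is given beside each. This setting also rests on the few residual degrees of freedom that 3 libraries per group leave. A call lost there is therefore not by itself evidence of correlation between genes. The estimate lay below the preset for the V-ATPase, ferroptosis and G1/S lists (0.0054, -0.015 and 0.0026) and above it for the other called lists. The self-contained test fry called 22 lists.

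Core autophagy genes leaned upward without a call of the list. Of 49 members tested, 22 were higher, 11 lower and 16 not called (22 higher and 12 lower adjusted over the list alone), and the camera test gave an adjusted p of 0.10. Without the genes that hold TGAGTA in the 3' UTR, the list was called at the preset correlation (adjusted p = 0.047), and with all genes and an estimated correlation it had an adjusted p of 0.27. RAB7A, a GTPase gene of late endosomes and autophagosome fusion, had a log2 fold change of 0.58 (SE 0.05), the autophagosome membrane gene MAP1LC3B 0.55 (SE 0.05), ATG4A 0.88 and ATG101 0.63. Among 20 genes of autophagy receptors, 3 were higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.14). NBR1, a receptor for ubiquitinated cargo whose 3' UTR holds CTGAGTA, fell from 181 ± 4.41 to 88.7 ± 4.29 CPM (SD, n = 3). The mitophagy receptor genes BNIP3 and BNIP3L and the gene CALCOCO1 fell by 1.15, 0.93 and 0.78 on the log2 scale. SQSTM1, the gene of the receptor p62, went the other way, from 361 ± 13.7 to 520 ± 50.6 CPM (log2 fold change 0.53, SE 0.06, adjusted p = 1.1e-06).

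Lysosomal hydrolase genes were divided, with 14 of 50 higher, 16 lower and 20 not called, and the same counts adjusted over the list alone (camera adjusted p = 0.78). With library size as the sole scaling, 15 were higher and 14 lower. The 12650 genes tested divided in similar shares, with 3946 higher, 3959 lower and 4745 not called under TMM scaling. Cathepsin genes went both ways. CTSL, CTSS, CTSC, CTSD and CTSB rose by log2 fold changes of 0.89, 0.84, 0.50, 0.27 and 0.18, whereas CTSF, CTSK and CTSO, chosen after their values were seen, fell by 0.55, 0.44 and 0.90. HEXA, a hexosaminidase subunit gene, fell by 0.55. CTSD shares part of its sequence with another gene. Of 33 lysosomal membrane protein genes, 9 were higher and 11 lower, also adjusted over the list alone (camera adjusted p = 0.78; with library size alone, 11 and 11). Median and mean of this list differed in sign. LAMP1 and LAMP2, abundant lysosomal membrane glycoproteins, fell by 0.35 (SE 0.05, adjusted p = 6.0e-06) and 0.18 (SE 0.05, adjusted p = 0.0028). SCARB2 and TMEM106B fell by 0.77 and 0.78, and the cholesterol exporter gene NPC1 and the gene OSTM1 rose by log2 fold changes of 0.56 and 0.91.

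Subunit genes of the V-ATPase, the proton pump that acidifies lysosomes, rose as a list (camera adjusted p = 0.0071; adjusted p = 0.27 with an estimated correlation). Of 21 members, 14 were higher and 2 lower, also adjusted over the list alone. ATP6V0B, ATP6V0D1 and ATP6V0C had log2 fold changes of 0.72, 0.58 and 0.56, the last of these in a gene that shares a large part of its sequence with another gene. ATP6AP2, an accessory subunit gene with CTGAGTAA in its 3' UTR, fell from 184 ± 4.16 to 78.9 ± 8.04 CPM (SD, n = 3). Genes of lysosome transcription and mTORC1 control divided into 12 higher and 15 lower of 34, also adjusted over the list alone (camera adjusted p = 0.67). With library size alone, 12 were higher and 12 lower. TFEB, a transcription factor gene of lysosome biogenesis, fell by 0.55 (SE 0.14, adjusted p = 0.0029), the mTORC1 inhibitor gene DDIT4 by 1.63, and the Rag GTPase genes RRAGC and RRAGA by 0.79 and 0.46, while NPRL3 rose by a log2 fold change of 0.63.

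Antioxidant genes included HMOX1, the gene of the heme-degrading enzyme heme oxygenase, which rose from 29.7 ± 1.74 to 150 ± 28.9 CPM (SD, n = 3; log2 fold change 2.33, SE 0.11, adjusted p = 2.0e-11). The NRF2 and antioxidant list had 19 of 40 members higher and 9 lower, also adjusted over the list alone, and was not called (camera adjusted p = 0.091). The ferritin subunit gene FTH1 rose by a log2 fold change of 0.79, and ABCC3 fell by 0.99. NFE2L2, which encodes NRF2 itself, had a log2 fold change of 0.07 (SE 0.05, adjusted p = 0.20). The ferroptosis and iron list, which holds HMOX1, FTH1 and PTGS2 too, rose with 17 of 28 members higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.0071; adjusted p = 0.27 with an estimated correlation). Its member SAT1, a polyamine acetyltransferase gene, rose by a log2 fold change of 1.00 (SE 0.05). Of 5 NADPH oxidase genes tested, 1 was higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.78), and median and mean differed in sign. NOXA1 and DUOX1 fell by 1.10 and 1.11. CYBA fell by 0.15 (adjusted p = 0.047), a call lost with DESeq2-type factors (adjusted p = 0.054), with library size alone (adjusted p = 0.12) and without si-NC library 1 or 2 or si-KNSTRN library 1 or 2 (adjusted p = 0.26, 0.17, 0.12 and 0.091).

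Inflammatory genes gave the strongest list result. Of 34 NF-kB and cytokine genes tested, 29 were higher, 1 lower and 4 not called (29 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 0.75 (camera adjusted p = 1.4e-13; adjusted p = 0.23 with an estimated correlation). CXCL8, the gene of the neutrophil chemokine interleukin 8 (chromosome 4, 73740569 to 73743716, GRCh38), rose from 350 ± 5.58 to 1378 ± 6.25 CPM (SD, n = 3). IL1A and IL6 had log2 fold changes of 2.45 (SE 0.06) and 1.98 (SE 0.05). Immediate early genes rose with 22 of 29 members higher and 3 lower, also adjusted over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.32 with an estimated correlation). Among them were IER3, the phosphatase genes DUSP5 and DUSP1 and the AP-1 gene JUNB, at 1.38, 1.87, 1.01 and 0.97. Interferon-stimulated genes were divided, with 17 of 49 higher and 22 lower (18 and 23 adjusted over the list alone), a camera adjusted p of 0.33, and a median and mean of opposite sign. GBP2, the RNA sensor gene DDX58, IFIT2 and PARP14 fell by 1.36, 0.96, 0.64 and 0.62.

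Apoptosis regulators had 13 of 39 members higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.15), and the list was called at the preset correlation without the genes that hold TGAGTA (adjusted p = 0.047; adjusted p = 0.32 with all genes and an estimated correlation). The death receptor gene FAS, with CTGAGTA in its 3' UTR, fell by 1.58, and PMAIP1 and TNFRSF10A rose by log2 fold changes of 0.55 and 0.83. Of 32 p53 targets, 13 were higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.30). CDKN1A, the gene of the cell cycle inhibitor p21, rose from 14.2 ± 1.23 to 73.5 ± 10.7 CPM (SD, n = 3; log2 fold change 2.36, SE 0.10, adjusted p = 7.9e-12). TIGAR rose by a log2 fold change of 1.10 and PLK2 fell by 0.85. Integrated stress response genes had 16 of 34 higher and 9 lower (16 and 11 adjusted over the list alone; camera adjusted p = 0.61), and within this list GDF15 rose by a log2 fold change of 3.62, and VLDLR and VEGFA fell by 1.11 and 0.88.

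Most hypoxia and glycolysis genes fell, with 31 of 38 lower and 6 higher (32 and 6 adjusted over the list alone). The list had a median log2 fold change of -0.57 (camera adjusted p = 1.1e-09, and 0.32 with an estimated correlation). PFKFB4, which encodes a regulator of glycolytic flux, and the enolase gene ENO2 fell by 1.69 and 1.13 on the log2 scale, beside CA9 and ALDOC. Cytosolic ribosomal protein genes also fell, with 51 of 74 lower and none higher (54 lower adjusted over the list alone; camera adjusted p = 1.1e-09; adjusted p = 0.46 with an estimated correlation). RPL34 and RPS6, both with TGAGTAA in the 3' UTR, fell by 0.98 and 0.89, and RPL3 and RPL13A by 0.74 and 0.64. Mitochondrial genome transcripts had 5 of 13 higher and none lower, also adjusted over the list alone (camera adjusted p = 0.14), and the list was called at the preset correlation without si-KNSTRN library 3 (adjusted p = 0.0074). With all libraries and an estimated correlation, its adjusted p was 0.77. ND5, ND3, ND2 and ND4, subunit genes of complex I, had log2 fold changes of 0.37, 0.29, 0.27 and 0.25. Nuclear genes of the respiratory chain had 21 of 59 higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.12), among them NDUFA6 (0.50), NDUFS6 (0.41), SDHB (0.35) and COX5A (0.30).

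The G2/M and mitosis list fell, with 44 of 75 members lower and 14 higher, also adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.50 with an estimated correlation). TOP2A, ASPM and the condensin gene NCAPD2 fell by 0.84, 0.71 and 0.50 on the log2 scale, and CKS2 rose by a log2 fold change of 0.63. The G1/S and DNA replication list had 28 of 60 lower and 15 higher, also adjusted over the list alone and 33 and 9 with upper-quartile factors (camera adjusted p = 0.046; adjusted p = 0.27 with an estimated correlation). This call was also lost with library size alone (adjusted p = 0.056), with the replicate number as a block (adjusted p = 0.052) and without si-NC library 3, si-KNSTRN library 1 or si-KNSTRN library 2 (adjusted p = 0.064, 0.058 and 0.053). The thymidylate synthase gene TYMS fell from 207 ± 1.30 to 85.9 ± 6.16 CPM (SD, n = 3), MCM3 by 1.05 and TK1 by 0.72, and the cyclin gene CCND1 rose by a log2 fold change of 0.83. The 3' UTRs of TYMS, MCM3, TOP2A and ASPM hold TGAGTA. Kinetochore genes, the group KNSTRN itself works with, were divided, with 15 of 40 higher and 15 lower, also adjusted over the list alone (camera adjusted p = 0.57; 16 and 15 with library size alone, 12 and 16 with upper-quartile factors). SPC24, NUMA1, KNTC1 and CENPU fell by 1.27, 0.53, 0.63 and 0.59. SPAG5, which encodes the kinastrin partner astrin, fell by 0.31 (SE 0.05, adjusted p = 5.1e-05). Of 11 replication-dependent histone genes, 2 were lower and none higher (1 lower adjusted over the list alone; camera adjusted p = 0.94), with a median and mean of opposite sign. H2AC11 fell by 1.64 (SE 0.43, adjusted p = 0.0031) and H2BC11 by 0.86 (SE 0.34, adjusted p = 0.035), both at low levels. They went from 0.920 ± 0.399 to 0.288 ± 0.122 CPM and from 0.854 ± 0.258 to 0.460 ± 0.0401 CPM. H2BC9 and H2AC6 had log2 fold changes of 0.48 (adjusted p = 0.068) and -0.21 (adjusted p = 0.19). The call of H2BC11 was lost with DESeq2 (adjusted p = 0.16) and without si-NC library 1 or 2 (adjusted p = 0.072 and 0.15) or si-KNSTRN library 1, 2 or 3 (adjusted p = 0.053, 0.075 and 0.078). H2BC9 passed with library size alone (adjusted p = 0.048) and without si-KNSTRN library 3 (adjusted p = 0.00996).

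Chaperone genes rose. Of 19 cytosolic heat shock genes, 18 were higher and none lower, also adjusted over the list alone (median log2 fold change 0.51; camera adjusted p = 1.8e-07; adjusted p = 0.27 with an estimated correlation). HSPA8 went from 2010 ± 87.0 to 3148 ± 41.0 CPM (SD, n = 3), and HSPH1, FKBP4 and HSPA1B had log2 fold changes of 0.88, 0.68 and 0.67, the last in a gene that shares a large part of its sequence with another gene. Chaperones of the endoplasmic reticulum had 15 of 25 higher and 7 lower (16 and 7 adjusted over the list alone; camera adjusted p = 0.039; adjusted p = 0.32 with an estimated correlation), and the call was lost without si-KNSTRN library 1 (adjusted p = 0.062). HERPUD1, SDF2L1 and HYOU1 rose by log2 fold changes of 0.98, 0.98 and 0.60, and the oxidase gene ERO1A fell by 0.75. Cholesterol synthesis genes rose with 14 of 24 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0073; adjusted p = 0.27 with an estimated correlation), including NSDHL (0.76), SQLE (0.57) and CYP51A1 (0.56). Fatty acid genes had 11 of 22 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.17). FASN and ACSL3 rose by log2 fold changes of 0.79 and 0.76, and the lipid droplet gene HILPDA and the desaturase gene SCD fell by 1.35 and 1.07.

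**Figure D3:**
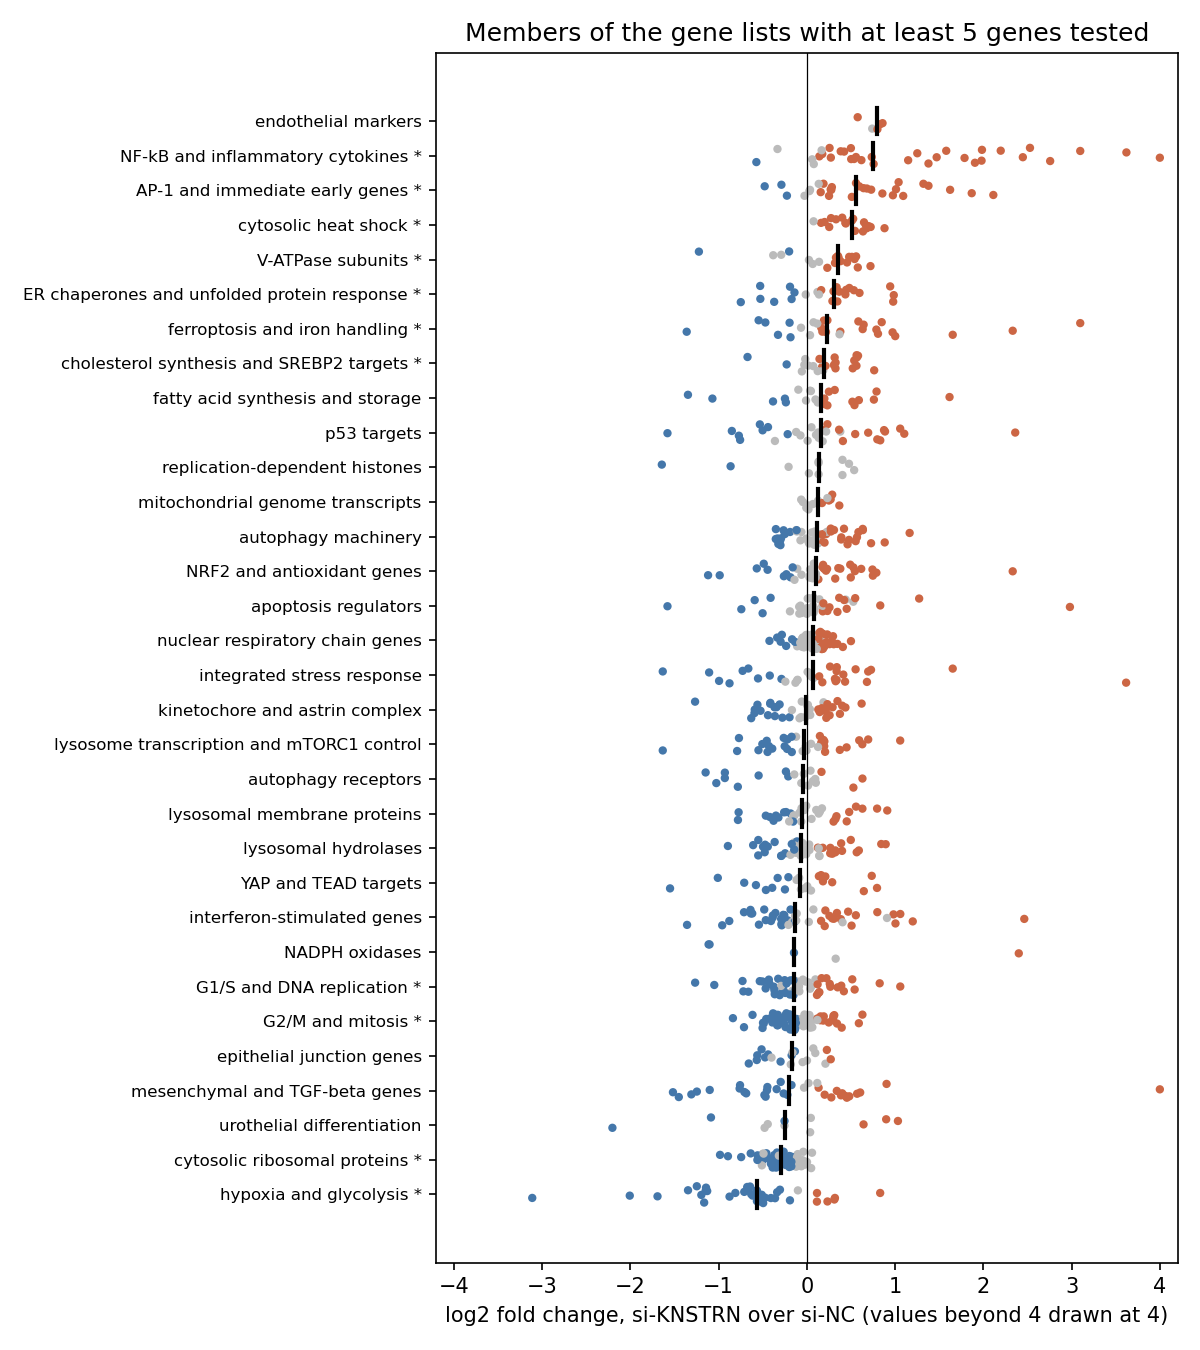
Log2 fold change of si-KNSTRN over si-NC for the members of the 32 gene lists tested, sorted by list median. Each point is a gene, orange if called higher, blue if called lower and grey if not called, the black bar is the list median, and an asterisk marks the 11 lists called by camera. NF-kB genes have a median of 0.75 and hypoxia and glycolysis genes the lowest, -0.57, and the 2 members beyond 4 are drawn at 4.

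Mesenchymal and TGF-beta genes had 13 of 34 higher and 18 lower, also adjusted over the list alone (camera adjusted p = 0.30). The integrin gene ITGB1 fell from 2231 ± 130 to 779 ± 114 CPM (SD, n = 3), and the lysyl oxidase gene LOX fell by 1.31, both with TGAGTA in the 3' UTR, while the urokinase receptor gene PLAUR rose by a log2 fold change of 0.90. Of 24 YAP and TEAD targets, 8 were higher and 9 lower, also adjusted over the list alone (camera adjusted p = 0.41). AXL, YAP1 and MYOF fell by 1.55, 1.01 and 0.58, and CCN2 rose by a log2 fold change of 0.79. The 3' UTR of AXL holds CTGAGTA and that of YAP1 holds TGAGTA. Epithelial junction genes had 2 of 19 higher and 9 lower (2 and 8 adjusted over the list alone; camera adjusted p = 0.18), with falls of 0.66 for PKP3, 0.47 for JUP and 0.44 for TJP1. Urothelial genes had 3 of 11 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.96), and the test pointed up while median and mean lay below 0. TBX3, TBX2 and PPARG had log2 fold changes of 1.03, 0.90 and 0.64, and ERBB3 fell by 1.09.

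Few markers of cells other than tumour epithelium passed the low-count filter, and erythroid markers had none tested of 10. Of 3 leukocyte markers tested, LCP1 rose from 1.70 ± 0.333 to 8.21 ± 0.908 CPM (SD, n = 3), CORO1A rose by a log2 fold change of 0.29 (adjusted p = 0.029) and CD14 had 0.34 (adjusted p = 0.24). The call of CORO1A was lost with DESeq2 (adjusted p = 0.098), with upper-quartile factors (adjusted p = 0.061) and without si-NC library 1 or 3 or si-KNSTRN library 1 (adjusted p = 0.055, 0.10 and 0.15). Of 3 fibroblast markers tested, FBLN1, PDGFRB and COL1A1 fell by 0.54, 1.88 and 0.26. The call of COL1A1 (adjusted p = 0.025) was lost with DESeq2 (adjusted p = 0.086) and without si-NC library 1 or 2 or si-KNSTRN library 3 (adjusted p = 0.088, 0.10 and 0.088). Of 5 endothelial markers tested, 4 were higher and none lower (camera adjusted p = 0.14), namely EGFL7 (0.58), ESAM (0.86), TIE1 (0.83) and ERG (0.80). The calls of ESAM and ERG were lost without si-NC library 3 (adjusted p = 0.068 and 0.11), and that of ERG also without si-NC library 1 or si-KNSTRN library 2 (adjusted p = 0.14 and 0.10) and with DESeq2 (adjusted p = 0.16). These 3 marker lists had the same counts adjusted over the list alone. TUG1, the one nuclear-retained RNA tested, fell by 0.33 (adjusted p = 0.0070).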

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

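The settings without genes that hold TGAGTA in the 3' UTR and without genes with near-identical copies were chosen after the data had been seen, and all others before. KNSTRN stayed called in all 14 other fits, with log2 fold changes from -1.67 to -1.57. A minimum of 2-fold left 384 higher and 430 lower genes, by construction of the stricter threshold. Without 1 library, higher genes numbered 3624 to 3842 and lower genes 3597 to 3859, and an adjusted p under 0.01 left 3284 and 3221; the other tests, scalings and filters gave 3489 to 4339 higher and 3379 to 4450 lower. Without genes that hold TGAGTA, 3232 higher and 2673 lower genes were left, and without near-identical copies 3925 and 3944. Camera called 11 lists, 0 with an estimated correlation (5 lists at an unadjusted p under 0.05) and 22 lists with fry, which asks another question; without 1 library it called 9 to 12. Of 157 named genes, 6 of the 153 called lost the call under some alternative and none changed sign. Libraries with the same number did not deviate together (correlations -0.06, 0.05 and -0.03), so the numbers were not read as pairs; with the replicate block, 3831 genes were higher, 3857 lower and 10 lists called. Depth sets the floor of 0.146 to 0.183 CPM for 3 reads. Calls that depended on 1 library were found for genes at low levels (ERG at 0.603 CPM in si-NC) and at high ones (CYBA at 411 CPM), and the cause was not tested.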

Other observations

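The gene groups in the first paragraph, the motif search as such, and the tests of other splits, of base composition, of each si-KNSTRN library for the motif, of interferon genes, of ATTTA, of left-out libraries for the NF-kB list and of copy families were chosen only after the values had been seen.

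Beyond the fixed lists, 11 groups read off gene symbols were examined because their members leaned one way, so their p-values describe that lean and are not independent evidence of it. Genes with UTP, NOP, RRP and NOL symbols, most of them in ribosome assembly, had 27 of 36 higher and 3 lower, with RRP9 at 1.09, NOP2 at 0.80 and NOL6 at 0.78 on the log2 scale (camera adjusted p = 6.8e-06; adjusted p = 0.10 with an estimated correlation), while ribosomal protein genes fell. Zinc finger genes with ZNF symbols had 220 of 431 lower and 31 higher (camera adjusted p = 1.1e-05; adjusted p = 0.10 with an estimated correlation). Proteasome subunits had 19 of 37 higher and 4 lower (camera adjusted p = 0.0044; adjusted p = 0.10 with an estimated correlation), and the 4 included PSMB8, PSMB9 and PSMB10 of the immunoproteasome, at -0.36, -0.39 and -0.35. Chaperonin subunits had 7 of 8 higher (camera adjusted p = 0.0017; adjusted p = 0.15 with an estimated correlation), and genes of mitochondrial import had 15 of 25 higher and 3 lower (camera adjusted p = 0.0030; adjusted p = 0.15 with an estimated correlation). Mitochondrial ribosomal proteins had 39 of 78 higher and 14 lower (camera adjusted p = 0.010; adjusted p = 0.27 with an estimated correlation), and RNA polymerase subunits 22 of 33 higher and 5 lower (camera adjusted p = 0.0021; adjusted p = 0.10 with an estimated correlation and 0.058 without genes that hold TGAGTA). Among ligands of the EGF receptor, EREG, AREG, HBEGF and TGFA rose by log2 fold changes of 1.95, 1.93, 1.81 and 0.86, and EGF fell by 1.36 (camera adjusted p = 0.010; adjusted p = 0.10 with an estimated correlation and 0.058 without genes that hold TGAGTA). Lysine demethylases (10 of 17 lower and 2 higher; camera adjusted p = 0.0057; adjusted p = 0.10 with an estimated correlation) and cilium genes with IFT and BBS symbols (13 of 22 lower and 3 higher; camera adjusted p = 0.010; adjusted p = 0.27 with an estimated correlation) leaned down. In the HOXB cluster 6 of 9 genes were lower and none higher, with HOXB9 at -1.21, and the group was not called (camera adjusted p = 0.051; adjusted p = 0.28 with an estimated correlation) except at the preset correlation without genes that hold TGAGTA (adjusted p = 0.032).

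Genes with CTGAGTA in the 3' UTR leaned lower relative to other genes: the word had the lowest z of 15611 words, -12.4, over 1396 genes (coefficient -0.20, SE 0.02), and TGAGTAA had the next, -12.0. A candidate explanation is seed-type silencing by the transfected siRNA, in which short matches to the start of the guide lower other mRNAs. The site classes went its way, with coefficients of -0.31 for the 8-base CTGAGTAA, -0.24 for either 7-base site and -0.12 for TGAGTA alone. The first and the last differed by -0.19 (SE 0.03). CTGAGTA had a coefficient of -0.09 (SE 0.02) in the coding sequence against -0.20 in the 3' UTR. These words were picked for their low z in 3' UTRs on the same fold changes. Both differences may therefore be partly built in, and their standard errors do not allow for that choice. Base composition is argued against by other words of the same bases without TGAGTA, whose lowest z was -3.77, and single deviating libraries by contrasts within si-NC, where the z farthest from 0 was 0.597, and by each si-KNSTRN library against the si-NC mean, with coefficients of -0.18, -0.19 and -0.22. KNSTRN itself holds CTGAGTAA in its coding sequence, in exon 5 of 9 (chromosome 15, 40389516 to 40389523, plus strand, GRCh38), but whether the siRNA was directed there stays open because its sequence was not used here, and an effect of KNSTRN loss on these genes was not tested apart from it. The z of each si-KNSTRN library against the other 2 was 4.72, 1.79 and -5.55 for libraries 1 to 3, the last also the farthest along the first principal component.

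NF-kB and inflammatory genes rose, and a response to transfected double-stranded RNA may be a cause, since both groups received an siRNA but of different sequence. An interferon response as its form is argued against by 41 interferon-stimulated genes outside the NF-kB list and without TGAGTA, of which 34.1% were higher and 46.3% lower. Longer life of mRNAs with AU-rich 3' UTRs stays open: the element TTATTTATT had a positive coefficient of 0.096 (SE 0.018) outside the NF-kB and immediate early lists and TATTTAT the highest z of all 15611 words, 7.47, while NF-kB members with and without the element had mean log2 fold changes of 1.24 and 1.19 (permutation p = 0.91, two-sided), and the 5 members without even ATTTA, too few to decide, had 0.61 (SE 0.52). A single library carrying the rise is argued against, as the median without any 1 library stayed at or above 0.70 and the list stayed called. Loss of KNSTRN and off-target effects of the siRNA both stay open, since a second siRNA was not analysed here.

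Near-identical gene copies differed between replicate libraries. BOLA2B, for example, had 13, 10 and 20 reads in si-NC and 13, 11 and 538 in si-KNSTRN libraries 1 to 3. Reads shared between copies and counted differently per library may be a cause. The 91 genes that share at least 90% of their windows had a median within-group SD of log2 CPM 2.50 times that of genes of similar count. This ratio measures the spread itself and cannot decide its cause. Reads moved between listed copies are argued against, because summed counts differed by over 1.5 times between si-KNSTRN libraries in 18 of 20 families. Between si-NC libraries they did so in 16 of the 20, so this spread was not particular to si-KNSTRN. No biological explanation was tested, and XAGE1B, RGPD5 and other such genes are best read as uncertain.

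For the count of 7905 called genes, 1 of the 10 splits of the 6 libraries into groups of 3 gave as many, the real one, and the highest of the others called 1 gene; 10 splits cannot give a share under 0.05.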
